A study of Mus musculus with 30 samples.

How the data were processed

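Per the labels, the samples were primary endothelial cells from the brains of untreated wild-type mice of both sexes at 2, 6, 12, 18 and 24 months, with 6 biological replicates per age (3 male and 3 female). How the cells were isolated, and whether each library holds cells of 1 mouse or of a pool, is not given in the sources used here. If pooled, the SDs describe pools and not single mice. Per the labels' protocols, full-length cDNA was made with the SMART-Seq v4 low-input kit, which primes on the poly(A) tail and amplifies by PCR, and libraries were made by tagmentation with Nextera XT. Neither step keeps the strand of the RNA or adds molecular identifiers, so reads from a gene and an overlapping antisense gene cannot be told apart and PCR copies are counted. Per the labels' protocols, 24 libraries were sequenced as paired ends and 6 as single ends of 50 bases on another instrument, and which libraries these are is not given in the sources used here. Instrument therefore entered no model, and if these 6 libraries share an age or a sex, its effect is part of that group's differences.

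The submitters' processing notes name FastQC 0.11.4, STAR 2.5.2b, MultiQC and HTSeq and the mouse builds GRCm38 and mm10, which are the same assembly. The authors deposited 1 table of read counts per library in the layout of STAR's gene counter, with 3 count columns (reads of either strand, and reads of each strand), 48795 genes and 4 lines that name no gene. The deposited counts are whole numbers that were not normalized. The column that ignores strand was used, since the forward-strand column held between 49.7 and 50.0% of the stranded counts in each library, which is what a kit without strand gives. The 4 lines that name no gene were left out of library sizes and tests. Among all reads counted they held 2.50 to 6.26% unmapped reads, 8.64 to 13.3% reads at several places, 3.82 to 13.1% reads outside genes and 3.61 to 4.21% reads over several genes. Reads at several places are lost from genes with near-identical copies, so that families such as the H2-Q genes are counted only where the copies differ.

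Gene symbols came from a gene name table and from the GENCODE M21 annotation of GRCm38. Of the 48795 gene identifiers 41341 matched the gene name table with their version and 48349 without it, and 48435 matched the annotation, which gave the coordinates (1-based). The annotation release the submitters used is not given in the sources used here. There were 72 symbols carried by more than 1 identifier.

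The design, the tests, the gene lists, the rule for naming genes and the first set of alternatives were fixed before the data were examined. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr grouped by age (minimum count 10, minimum total count 15), which left 16844 genes with at least 99.9% of the gene counts of every library and put aside 31951. Libraries were scaled by TMM. The quasi-likelihood model was fitted with robust dispersion to all 30 libraries, and p-values were adjusted by the method of Benjamini and Hochberg, with a threshold of 0.05. The slope on age in months was fitted with sex as a covariate, which follows the design text, and slopes are given as the change over the 22 months from 2 to 24. The contrasts of 6, 12, 18 and 24 with 2 months took age as a factor with sex as a covariate. The departure from a straight line was the joint test of 3 further polynomial terms of age. Sex was tested with age as a factor, the interaction as the product of sex and age in months, and the slopes in the 15 male and the 15 female libraries in separate fits. CPM values use TMM-scaled library sizes. An SE of a log2 change was derived from its F statistic.

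There were 46 lists, 32 of genes and 14 of markers of other cells. The gene lists were endothelial identity, tight junctions, adherens junctions, blood-brain barrier solute carriers, ABC efflux transporters, caveolae and transcytosis receptors, basement membrane, integrins, and matrix proteases and inhibitors. Others held genes linked to cerebral haemorrhage, SRF and MRTF targets, immediate early and dissociation response, MHC class I presentation, interferon response, leukocyte adhesion and NF-kB, and haemostasis and vascular tone. Further lists were VEGF and angiogenesis, Notch and arterial, capillary, venous, Wnt and beta-catenin, and TGF-beta and BMP. The remaining gene lists were nuclear oxidative phosphorylation, mitochondrially encoded genes, cytosolic ribosomal proteins, chaperones, cell cycle, p53 targets and cell cycle inhibitors, antioxidant defence, circadian clock, cholesterol synthesis, and DNA methylation and histone modifiers. The marker lists were for pericytes, smooth muscle, fibroblasts, astrocytes, oligodendrocytes and their precursors, neurons, microglia, border macrophages, T and NK cells, B and plasma cells, neutrophils, erythroid cells, and choroid plexus and ependyma. The lists were written from general knowledge of the cells. Lists were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the 46 lists, and again with the correlation estimated from the data and with fry. Scores of marker lists are means of log2(CPM + 0.5).

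Genes were named by a fixed rule: the 12 steepest rising and 12 steepest falling genes on age with a mean of at least 5 CPM and the same sign in both sexes, and up to 4 members of each list with the lowest p on age. To these came a set of barrier and vessel genes always given, 5 genes per direction for sex with the sex-linked check genes, up to 5 genes of lowest p for the departure from a line, and 3 genes per direction for each pair of ages. No gene met the rule for the interaction. Some genes that met the rule are not reported here.

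The alternatives fixed in advance were RLE scaling, no filter on low counts, DESeq2 1.42.0, limma-voom, no sex covariate, the share of reads outside genes as a covariate, and 2 surrogate variables (sva 3.50.0). They further included log2 of age, each age left out, only the libraries of the ages compared, the list tests above, and each library left out in turn. The alternatives chosen after seeing the data were a term for the 6- and 24-month libraries, only the 2-, 12- and 18-month libraries, only the 6- and 24-month libraries, the 3 female libraries of 6 months left out, and the share of counts in longer genes as a covariate. Other splits of the libraries were drawn 100 times per result, the real split included, with a fixed seed.

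The fits were tested on simulated counts with the depths and means of the 30 libraries and 200 genes changed by known folds. On the age slope 40.3% of the genes changed 1.5-fold over 22 months were recovered, 85.1% of those changed 2-fold and 98.5% of those changed 4-fold. For 24 against 2 months these shares were 37.3, 71.6 and 81.8%, for 18 against 2 months 50.7, 70.1 and 93.9%, for 12 against 2 months 41.8, 68.7 and 95.5%, and for 6 against 2 months 58.2, 70.1 and 89.4%. They were 46.3, 80.6 and 92.4% for the departure from a line, 77.6, 89.6 and 95.5% for sex and 13.4, 44.8 and 72.7% for the interaction. They were 26.9, 56.7 and 87.9% for the slope in males and 22.4, 44.8 and 84.8% for the slope in females. Of the genes called in these simulations 8.18% had not been changed for the slope in females, 6.80% for 12 against 2 months and 6.56% for the slope in males, above the 5% aimed at, and 3.31 to 4.67% in the other 7 comparisons. Of 6 lists changed 1.5-fold 5 were recovered and none of 30 untouched lists was called. The simulated genes were drawn independently, whereas the estimated correlation within real lists reached 0.83 (microglia markers). The simulation therefore does not show how often lists of correlated genes are called falsely. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 read the tables and drew the figures.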

Results

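RNA was sequenced from primary endothelial cells taken from the brains of untreated wild-type mice aged 2, 6, 12, 18 and 24 months. Endothelial cells line the blood vessels, and in the brain they form the blood-brain barrier through tight junctions, a small set of transporters and little vesicular transport. Each age had 6 libraries, 3 from males and 3 from females, which makes 30 libraries that the study's design counts as biological replicates. The study asked how endothelial expression changes with age, with regression on age after correction for sex, and set this beside barrier integrity and the risk of bleeding into the brain. Each library was full-length cDNA amplified from a small amount of RNA. Counts in genes per library ranged from 24588877 to 33187952 at 2 months, 24140980 to 42928057 at 6 months, 26141837 to 35403873 at 12 months, 29335323 to 41372814 at 18 months and 35868349 to 50464366 at 24 months. Levels are given as CPM, which scales each library to the same total. A count of 0 allowed up to 3 counts, which is 0.0594 to 0.124 CPM depending on the library. Such limits cover counting error only.

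The sex labels matched the sex-linked transcripts in all 30 libraries. Ddx3y, a Y-linked helicase gene, ranged from 93.3 to 159.7 CPM in the male libraries and reached at most 0.036 CPM in the female ones. Xist, the X-linked RNA that silences one X chromosome, ranged from 21.2 to 133 CPM in the female libraries and reached at most 1.83 CPM in the male ones. All 75 pairs of replicates differed by more than sampling noise, with a chi-square per degree of freedom of 15.25 to 189.5. Endothelial transcripts were abundant, with means over the 30 libraries of 4573 CPM for the glucose transporter Slc2a1, 4116 CPM for the tight junction claudin Cldn5 and 1038 CPM for the adhesion protein Pecam1. Transcripts of other brain cells were present at lower levels, such as the myelin gene Mbp at 217 CPM, the astrocyte enzyme gene Aldoc at 148 CPM and the microglial receptor gene P2ry12 at 26.2 CPM.

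The ages differed in the make-up of the libraries as well. Reads that mapped outside annotated genes made up 5.06 ± 0.971% (SD, n = 6) at 2 months, 5.69 ± 1.26% at 6 months, 6.03 ± 0.676% at 12 months, 10.4 ± 2.13% at 18 months and 7.19 ± 1.76% at 24 months. The share of counts in genes of above-median exon length was 53.9 ± 1.72% at 2 months, 49.7 ± 4.51% at 6 months, 52.5 ± 3.38% at 12 months, 57.8 ± 2.42% at 18 months and 53.9 ± 1.65% at 24 months. The lowest shares of longer genes were in the 3 female libraries of 6 months (45.9, 44.3 and 47.6%) and male 12-month replicate 1 (46.6%). Counts of mitochondrially encoded genes made up 0.562 ± 0.144% at 2 months and between 0.882 and 1.07% on average at the later ages.

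**Figure D1:**
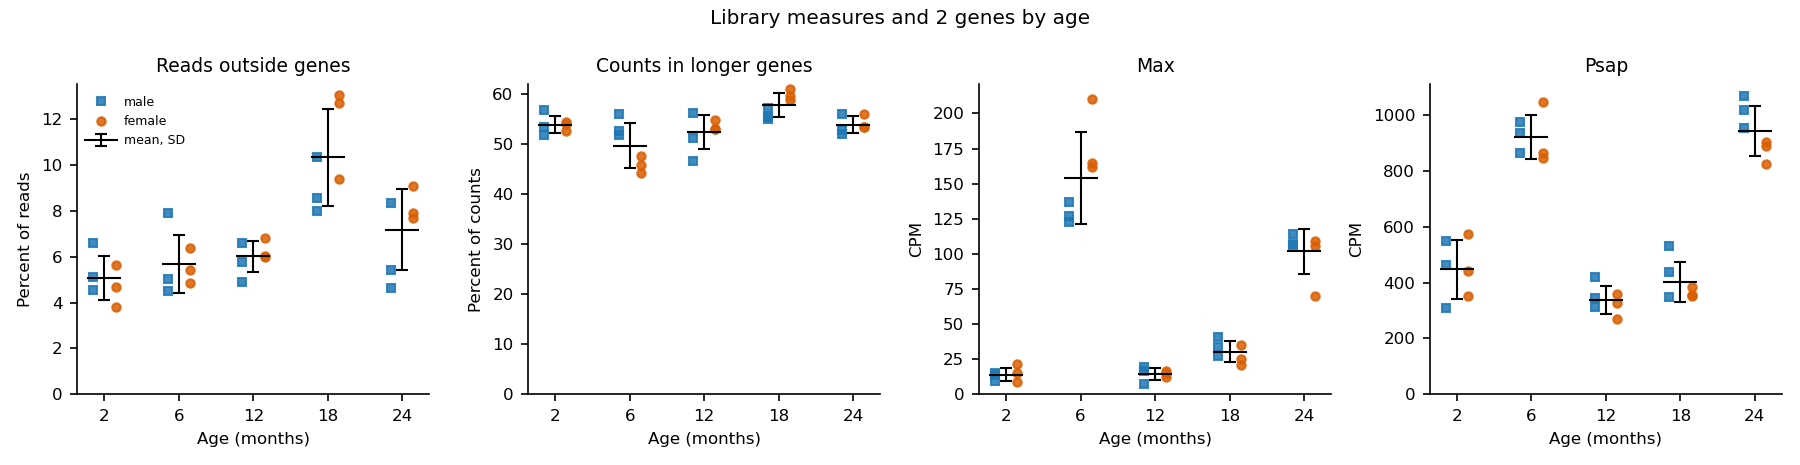
Each point is 1 library (squares male, circles female) and the bars are the mean and SD of 6 libraries, with age in months on the x axis and, by panel, the percent of reads outside genes, the percent of counts in longer genes, and Max and Psap in CPM on the y axis. Reads outside genes averaged 10.4% at 18 months, and Max averaged 153.9 CPM at 6 months and 101.9 CPM at 24 months against 13.8 to 30.2 CPM at the other ages.

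Across the 5 ages, 1843 of the 16844 genes tested had a slope on age that passed, 964 rising and 879 falling (edgeR, adjusted p under 0.05, n = 30). Ntn4, which encodes the secreted laminin-related protein netrin-4 (chromosome 10, 93640681 to 93747207, GRCm38), rose from 52.0 ± 13.1 CPM (SD, n = 6) at 2 months through 77.5 ± 5.33, 159.6 ± 57.3 and 178.9 ± 23.7 CPM to 223.6 ± 25.2 CPM at 24 months. Its fitted change over the 22 months was 2.09 ± 0.18 log2 (SE, adjusted p = 7.16e-09), and all 6 libraries of 24 months lay above the 2-month mean. Aplnr, the receptor for the angiogenic peptide apelin (chromosome 2, 85136225 to 85139923), fell by 4.81 ± 0.45 on the log2 scale (adjusted p = 2.73e-08). It went from 91.1 ± 21.8 CPM at 2 months to 9.60 ± 3.21 CPM at 6 months and 2.70 ± 1.61 CPM at 24 months. Oas2, an interferon-induced sensor of double-stranded RNA, rose from 13.8 ± 3.96 to 61.1 ± 2.15 CPM (2.31 ± 0.23 log2, adjusted p = 4.63e-08).

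Other rising genes among those with the steepest slopes were BC107364, the chemokine-binding receptor Ackr1, the Ras exchange factor Rasgrf2, the cholesterol 25-hydroxylase Ch25h, and the MHC class I gene H2-Q6, followed by the neuronal nitric oxide synthase Nos1, the lactate exporter Slc16a3, the adhesion molecule L1cam and the secreted glycoprotein Lrg1. Their fitted rises over 22 months ran from 2.08 log2 for Lrg1 to 3.39 log2 for BC107364, and for each of them all 6 libraries of 24 months exceeded the 2-month mean. H2-Q6 (chromosome 17, 35424850 to 35430055) averaged 9.47 ± 5.44 CPM at 2 months and 159.2 ± 72.8 CPM at 24 months, but 1 female library of 6 months had 472.2 CPM. That library also had a mean log2 score of 8.45 on the MHC class I list, against 6.53 to 7.10 in the others of that age. On the interferon response list it had 7.28, against 6.33 to 6.62. H2-Q6 belongs to a family of near-identical H2-Q genes between which reads can be split. Its call was also lost with DESeq2, so its value is uncertain. The other 11 of the 12 steepest falling genes were the apelin gene Apln, Vat1l, Lurap1l, the potassium channel subunit Kcne2, the adaptor Samsn1, the folate receptor Folr1, Morn4, the amino acid transporter Slc7a10, Calml4, the protease Klk8 and the ligand Wnt6. Their fitted changes lay between -1.95 log2 for Vat1l and -1.60 log2 for Wnt6. Kcne2 and Folr1 are also markers of choroid plexus, whose marker group was lower with age in these libraries as given with the marker genes. For the other falling genes, a share from cells other than endothelium was not tested. In the 30 fits that each left out 1 library, the calls of Morn4, Calml4, Folr1 and Apln ended in 16, 13, 7 and 6 fits and that of Ackr1 in 1.

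**Figure D2:**
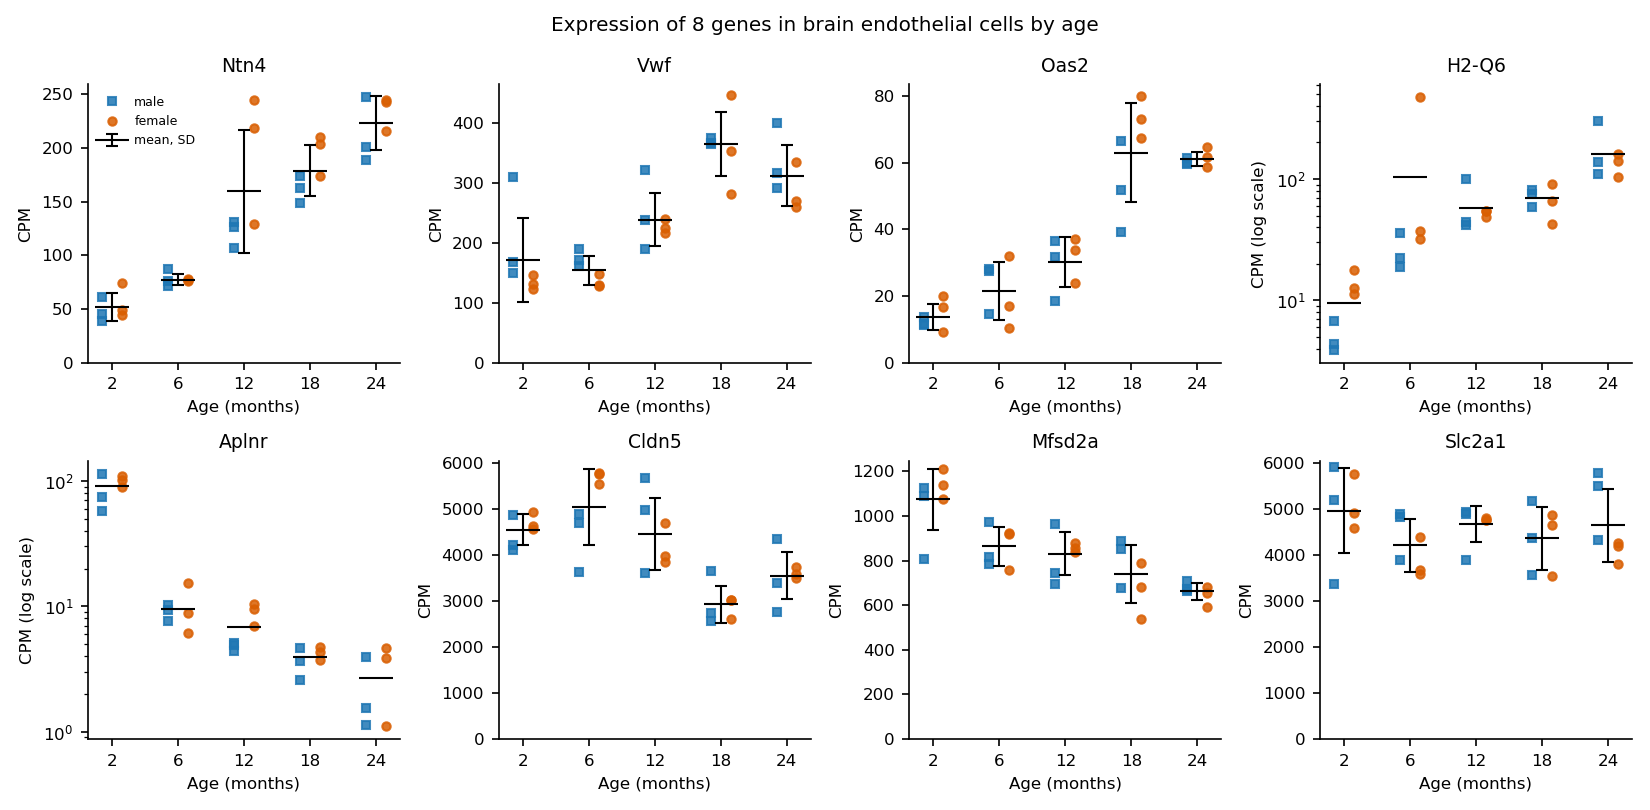
Points are single libraries (squares male, circles female) and horizontal bars the mean of 6 libraries, in CPM against age in months, for 8 genes, with the SD as whiskers except for Aplnr and H2-Q6, which are on a log axis. Ntn4 rose from a mean of 52.0 CPM at 2 months to 223.6 CPM at 24 months, and Aplnr fell from 91.1 to 2.70 CPM.

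The share of reads outside genes itself differed between the ages. With that share as a covariate on the slope 402 genes passed, 360 of them among the 1843. The median size of the slope over the 1843 genes went from 0.61 to 0.398 log2 over 22 months while its median SE went from 0.153 to 0.165, and 99.8% of the genes had the same sign. Without the 2-month libraries 886 genes passed, and without the 18-month libraries 713.

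Genes of the barrier's tight junctions were lower or not different with age. Of the 20 tight junction genes 4 fell and none rose over all genes tested, and 4 fell when adjusted over the list alone. Cldn5 (chromosome 16, 18776847 to 18778262), the main claudin of brain endothelium, was at 4559 ± 331 CPM at 2 months, 5056 ± 827 CPM at 6 months, 2937 ± 403 CPM at 18 months and 3559 ± 513 CPM at 24 months. Its slope over 22 months was -0.59 ± 0.14 log2 (adjusted p = 4.63e-03). The junctional adhesion molecule F11r (-0.30 ± 0.07 log2), the tricellular junction protein Lsr (-0.35 ± 0.10 log2) and the polarity gene Pard6g (-0.91 ± 0.16 log2) fell as well. The slope of Ocln was -0.26 ± 0.15 log2 (adjusted p = 0.263) and that of the scaffold gene Tjp1 0.28 ± 0.24 log2 (adjusted p = 0.485). As a group the list did not pass (camera, adjusted p = 0.121). Of 18 adherens junction genes 2 fell, Nectin3 (-1.05 ± 0.15 log2) and the N-cadherin gene Cdh2 (-1.11 ± 0.24 log2), and 2 did so adjusted over the list alone, with a group p of 0.346 after adjustment. The VE-cadherin gene Cdh5, Pecam1 and Ctnnb1 did not pass, with slopes of 0.14, 0.17 and -0.20 log2. With reads outside genes as a covariate Cldn5, F11r and Lsr no longer passed.

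Transporters of the barrier were lower as a group after 2 months. The mean log2 score of the solute carriers was 9.39 at 2 months. It was 9.09, 9.06, 9.11 and 9.06 at 6, 12, 18 and 24 months, so the group did not fall steadily. Of 23 solute carriers 6 fell and 1 rose, and 9 fell and 1 rose when adjusted over the list alone (camera, adjusted p = 6.22e-05; adjusted p = 0.492 with an estimated correlation). Mfsd2a, the lysolipid transporter that limits vesicular transport across the barrier, fell by 0.63 ± 0.10 on the log2 scale (adjusted p = 5.67e-05), from 1075 ± 138 CPM at 2 months to 661.9 ± 39.9 CPM at 24 months. The male 2-month library that was highest in astrocyte, microglia and smooth muscle markers had 809.6 CPM. The glutamine transporter Slc38a5 fell by 1.20 ± 0.19 and the monocarboxylate transporter relative Slc16a4 by 0.53 ± 0.09 on the log2 scale, and the taurine transporter Slc6a6 rose by 0.77 ± 0.12. Slc2a1 stayed between 4213 ± 572 and 4964 ± 924 CPM at the 5 ages (slope -0.05 ± 0.11 log2, adjusted p = 0.826). Of 9 ABC efflux transporters Abcb1b and Abcc1 rose and Abcg2 and Abcg1 fell, both over all genes and adjusted over the list alone, and the main P-glycoprotein gene Abcb1a had a slope of 0.24 ± 0.12 log2 (adjusted p = 0.199). Their group did not pass (adjusted p = 0.623). Of 15 genes of caveolae and transcytosis receptors the alkaline phosphatase gene Alpl and the insulin receptor gene Insr rose, each by 0.66 log2, none fell and the same 2 rose adjusted over the list alone (group adjusted p = 0.802). The caveolin gene Cav1 (-0.04 ± 0.12 log2) and the fenestral diaphragm gene Plvap (-0.88 ± 0.33 log2, adjusted p = 0.0785) did not pass. Abcb1b, Abcc1, Abcg2 and Insr lost their calls with reads outside genes as a covariate.

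Genes of the vessel wall's matrix moved in both directions. Of 16 basement membrane genes Sparc, a collagen-binding glycoprotein, fell by 1.06 ± 0.15 on the log2 scale (adjusted p = 2.05e-05), and the laminin gene Lama5 (0.53 ± 0.14 log2) and the collagen gene Col18a1 (0.72 ± 0.23 log2) rose. Adjusted over the list alone, 3 rose and 2 fell, and the group did not pass (adjusted p = 0.696). The collagen IV genes Col4a1 and Col4a2, in which mutations lead to brain haemorrhage, had slopes of -0.20 ± 0.16 and -0.25 ± 0.15 log2 (adjusted p = 0.437 and 0.308). Of 11 integrin genes Itga4 fell by 1.56 ± 0.31 and Itgb5 rose by 0.61 ± 0.19 on the log2 scale, with 1 in each direction adjusted over the list alone and a group adjusted p of 0.506. The sign of Itgb5 turned in the 2-, 12- and 18-month libraries alone (-0.16 log2). Of 17 proteases and inhibitors 3 rose and none fell, also when adjusted over the list alone (group adjusted p = 0.294). They were Reck, a membrane inhibitor of metalloproteases that also acts in Wnt7 signalling (0.73 ± 0.11 log2), the metalloprotease Adamts9 (1.35 ± 0.32 log2) and the gelatinase Mmp9. Mmp9 averaged 0.264 CPM over the libraries and lay close to the detection limit. Lama5, Col18a1, Itgb5 and Adamts9 lost their calls with reads outside genes as a covariate.

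Of 24 genes linked to cerebral haemorrhage or small vessel disease 2 rose and 2 fell, and 3 rose and 3 fell adjusted over the list alone (group adjusted p = 0.256). Htra1, the serine protease mutated in a hereditary small vessel disease, fell by 1.10 ± 0.15 on the log2 scale (adjusted p = 1.65e-05), and the cystatin gene Cst3 fell by 0.59 ± 0.17. Heg1, the partner of the cavernous malformation protein Krit1, rose by 0.45 ± 0.13 and Notch3 rose too (adjusted p = 7.47e-03). Notch3 is also a marker of pericytes, whose marker group was higher with age. Astrocyte and choroid plexus markers were lower with age, and whether cells other than endothelium shared in the falls of Htra1 and Cst3 was not tested. Of 27 targets of serum response factor (SRF) and its cofactors 4 rose and 2 fell, the same numbers as adjusted over the list alone (group adjusted p = 0.559). The matricellular gene Ccn1 rose by 1.47 ± 0.28 and the non-muscle myosin gene Myh9 by 1.17 ± 0.20 on the log2 scale. The cytoplasmic actin gene Actg1 rose by 0.88 ± 0.26 and the calponin gene Cnn3 fell by 0.47 ± 0.08. Srf itself had a slope of -0.03 ± 0.13 log2 (adjusted p = 0.906). Cst3, Heg1, Notch3 and Actg1 lost their calls with reads outside genes as a covariate.

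Genes of leukocyte adhesion and NF-kB signalling rose as a group (camera, adjusted p = 2.44e-03; adjusted p = 0.499 with an estimated correlation). Of 20 members 6 rose and 1 fell, and 9 rose and 1 fell adjusted over the list alone. The male 18-month library, replicate 2, had a mean log2 score of 6.496 on this list, against 4.93 to 5.52 in the other 5 of that age, and the highest venous and neutrophil scores of the 30 libraries (6.71 and 2.93). Without it the list's adjusted p was 1.26e-03. The prostaglandin synthase gene Ptgs2 rose by 2.04 ± 0.32 log2 (adjusted p = 8.50e-05) and the adhesion molecule gene Icam1 by 0.57 ± 0.16. The P-selectin gene Selp rose by 3.15 ± 0.92 log2 from a low level (mean 1.60 CPM), and Nfkb1 fell by 0.33 ± 0.08. Vcam1 had a slope of 0.62 ± 0.21 log2 (adjusted p = 0.0522). Vwf, which encodes the platelet-binding von Willebrand factor, rose by 1.22 ± 0.17 log2 (adjusted p = 1.75e-05), from 170.8 ± 69.7 CPM at 2 months to 364.0 ± 52.6 CPM at 18 months and 311.7 ± 51.2 CPM at 24 months, although 1 male library of 2 months had 309.5 CPM. Vwf and Selp were the 2 of 15 haemostasis and vascular tone genes that rose, over all genes and adjusted over the list alone, and none fell (group adjusted p = 0.873). Of 13 venous genes 4 rose and 2 fell, and 6 rose and 2 fell adjusted over the list alone, with Tmsb10 and Slc38a5 as the falling ones (group adjusted p = 0.127). Selp, Ackr1, Nfkb1 and Tmsb10 lost their calls with reads outside genes as a covariate.

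Of 18 genes of MHC class I presentation, H2-Q6 and Nlrc5, the transactivator of MHC class I, rose and none fell, also when adjusted over the list alone (group adjusted p = 0.121). Nlrc5 rose by 1.49 ± 0.34 log2 (adjusted p = 4.63e-03), and H2-Q7 had a slope of 1.91 ± 0.71 log2 that did not pass (adjusted p = 0.0805). Of 34 interferon response genes the RNA sensor Ifih1 (0.52 ± 0.14 log2) and Ifit2 (0.63 ± 0.19 log2) rose and Ifi35 fell by 0.32 ± 0.10, with the same numbers adjusted over the list alone (group adjusted p = 0.457). Ifih1, Ifit2, Ifi35 and Nlrc5 lost their calls with reads outside genes as a covariate.

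Angiogenic genes did not move together. Of 16 genes of VEGF signalling and angiogenesis 3 rose and 2 fell, and 4 rose and 4 fell adjusted over the list alone (group adjusted p = 0.506). The Tie2 ligand Angpt2 rose by 0.73 ± 0.14, the vasodilator peptide gene Adm by 0.86 ± 0.19 and the VEGF family gene Pgf by 1.09 ± 0.28 on the log2 scale, and Aplnr and Apln fell. Of 20 Notch and arterial genes 3 rose and none fell, also adjusted over the list alone, with a group adjusted p of 0.121. They were Stmn2 (1.45 ± 0.29 log2), the Notch ligand Jag2 (0.79 ± 0.18 log2) and the kinase Bmx (0.43 ± 0.14 log2). Capillary genes fell as a group (camera, adjusted p = 9.82e-03, and 0.234 with an estimated correlation). Their mean log2 score was 9.91 at 2 months and 9.66, 9.70, 9.76 and 9.62 at 6, 12, 18 and 24 months. Of 12 genes 3 fell, also adjusted over the list alone, led by the carbonic anhydrase Car4, which fell by 0.96 ± 0.09 on the log2 scale (adjusted p = 4.63e-08). Of 20 Wnt and beta-catenin genes Reck and the co-receptor Lrp6 (0.56 ± 0.12 log2) rose. The feedback inhibitor Nkd1 (-0.94 ± 0.12 log2) and the transcription factor Tcf7 (-0.28 ± 0.09 log2) fell, as many as adjusted over the list alone (group adjusted p = 0.314). Of 23 TGF-beta and BMP genes 4 rose and 1 fell, and 4 rose and 3 fell adjusted over the list alone (group adjusted p = 0.773). The inhibitory Smad7 rose by 0.90 ± 0.21 log2 and the receptor gene Bmpr2 by 0.50 ± 0.12 log2. Of 22 endothelial identity genes the transcription factor Erg had a rising slope (1.14 ± 0.27 log2) and Sox18 and Cldn5 fell, and 1 rose and 4 fell adjusted over the list alone (group adjusted p = 0.795). The course of Erg was uneven, at 24.7 ± 2.91, 61.8 ± 7.30, 29.7 ± 3.86, 75.2 ± 18.2 and 71.4 ± 11.7 CPM from 2 to 24 months. Apln, Jag2, Bmx, Lrp6, Tcf7, Smad7, Bmpr2, Erg and Sox18 lost their calls with reads outside genes as a covariate.

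Of the 46 lists 15 passed on age with camera, 5 higher and 10 lower. In 8 of 100 splits of the libraries, the real one included, as many passed. Chaperone genes fell together, 16 of 26 with none rising, and 20 fell adjusted over the list alone (camera, adjusted p = 3.93e-13; adjusted p = 0.234 with an estimated correlation). The HSP90 gene Hsp90ab1 fell by 0.98 ± 0.18 and the subunit gene Cct5 of the cytosolic chaperonin by 0.53 ± 0.09 on the log2 scale. Of 40 nuclear genes of oxidative phosphorylation 6 fell and none rose, and 12 fell adjusted over the list alone (camera, adjusted p = 1.61e-10; adjusted p = 0.560 with an estimated correlation). Among them were the ATP synthase gene Atp5b (-0.46 ± 0.11 log2) and the complex III gene Uqcrc1 (-0.38 ± 0.08 log2). Of the 13 mitochondrially encoded genes listed, 7 were among the genes tested. Whether the loss of reads at several places lowered their counts was not tested. None of the 7 passed, with a median slope of 0.27 log2 and mt-Co1 highest at 0.53 ± 0.18 log2 (adjusted p = 0.0583). Adjusted over the list alone 1 rose (camera, group adjusted p = 0.117). Of 44 cytosolic ribosomal protein genes 2 fell and none rose, Rpl27 among the falling ones, and 2 fell adjusted over the list alone (camera, adjusted p = 1.35e-03, and 0.677 with an estimated correlation). The mean log2 score of this list at 2 months was 3.74, against 7.06 for the oxidative phosphorylation list. Whether the loss of reads at several places lowered the ribosomal counts was not tested. Targets of p53 and cell cycle inhibitors fell, 5 of 17 over all genes and 7 adjusted over the list alone, with camera's adjusted p = 2.08e-03 and adjusted p = 0.0309 with an estimated correlation. This was the only list on age to pass that way. Its falling genes included the pro-apoptotic gene Bbc3 (-0.64 ± 0.14 log2) and the CDK inhibitor Cdkn2b (-0.61 ± 0.13 log2), while Cdkn1a, which encodes p21, had a slope of -0.77 ± 0.31 log2 (adjusted p = 0.105). None of the 22 cell cycle genes passed, over all genes or adjusted over the list alone (edgeR, group adjusted p = 0.873). With reads outside genes as a covariate Atp5b, Uqcrc1, Cdkn2b, Rpl27 and the oxidative phosphorylation and ribosomal lists lost their calls, and the ribosomal list turned with the share of counts in longer genes as a covariate (adjusted p = 0.754).

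Of 20 antioxidant genes 1 rose and 3 fell, and 1 rose and 6 fell adjusted over the list alone (camera, adjusted p = 6.92e-03; adjusted p = 0.624 with an estimated correlation). The mean log2 score of this list was 6.41, 6.46, 6.36, 6.10 and 6.37 from 2 to 24 months, lowest at 18 months and with no steady fall. The catalase gene Cat stood at -0.51 ± 0.09 log2 and the sulfiredoxin gene Srxn1 at 0.52 ± 0.13 log2. Of 17 cholesterol synthesis genes 1 rose and 2 fell, over all genes and adjusted over the list alone (camera, adjusted p = 0.0360; adjusted p = 0.624 with an estimated correlation). Fdft1, which makes squalene, stood at -0.44 ± 0.12 log2 and Lss, which closes its rings, at 0.66 ± 0.17 log2. Clock genes rose, 6 of 16 over all genes and adjusted over the list alone (camera, adjusted p = 6.92e-03; adjusted p = 0.624 with an estimated correlation). Among them were Per3 (1.20 ± 0.26 log2) and Bhlhe40 (0.93 ± 0.21 log2). The mean log2 score of the clock list was 4.832, 4.585, 5.058, 5.393 and 5.187 from 2 to 24 months, with SDs within ages of 0.421 to 0.498. The hour of collection entered no model of age or of sex. Of 22 immediate early genes, which respond within minutes to stimulation and to tissue dissociation, 7 rose and 1 fell, and 11 rose and 2 fell adjusted over the list alone (camera, adjusted p = 0.0104; adjusted p = 0.624 with an estimated correlation). Egr1 rose by 1.52 ± 0.29 and Nr4a1 by 1.10 ± 0.25 log2. Of 24 modifiers of DNA methylation and histones 4 rose and 2 fell, and 5 rose and 2 fell adjusted over the list alone (group adjusted p = 0.208). The class II deacetylase gene Hdac9 rose by 1.64 ± 0.20 log2 (adjusted p = 2.71e-06) and the deacetylase gene Sirt2 fell by 0.27 ± 0.08. With reads outside genes as a covariate Cat, Fdft1, Lss, Per3, Bhlhe40 and Sirt2 lost their calls, and the antioxidant list turned (adjusted p = 0.768). The cholesterol list lost its call in some fits without 1 library (adjusted p up to 0.122, without 24-month replicate 2), and the immediate early list without 24-month replicate 1 (adjusted p = 0.0610).

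**Figure D3:**
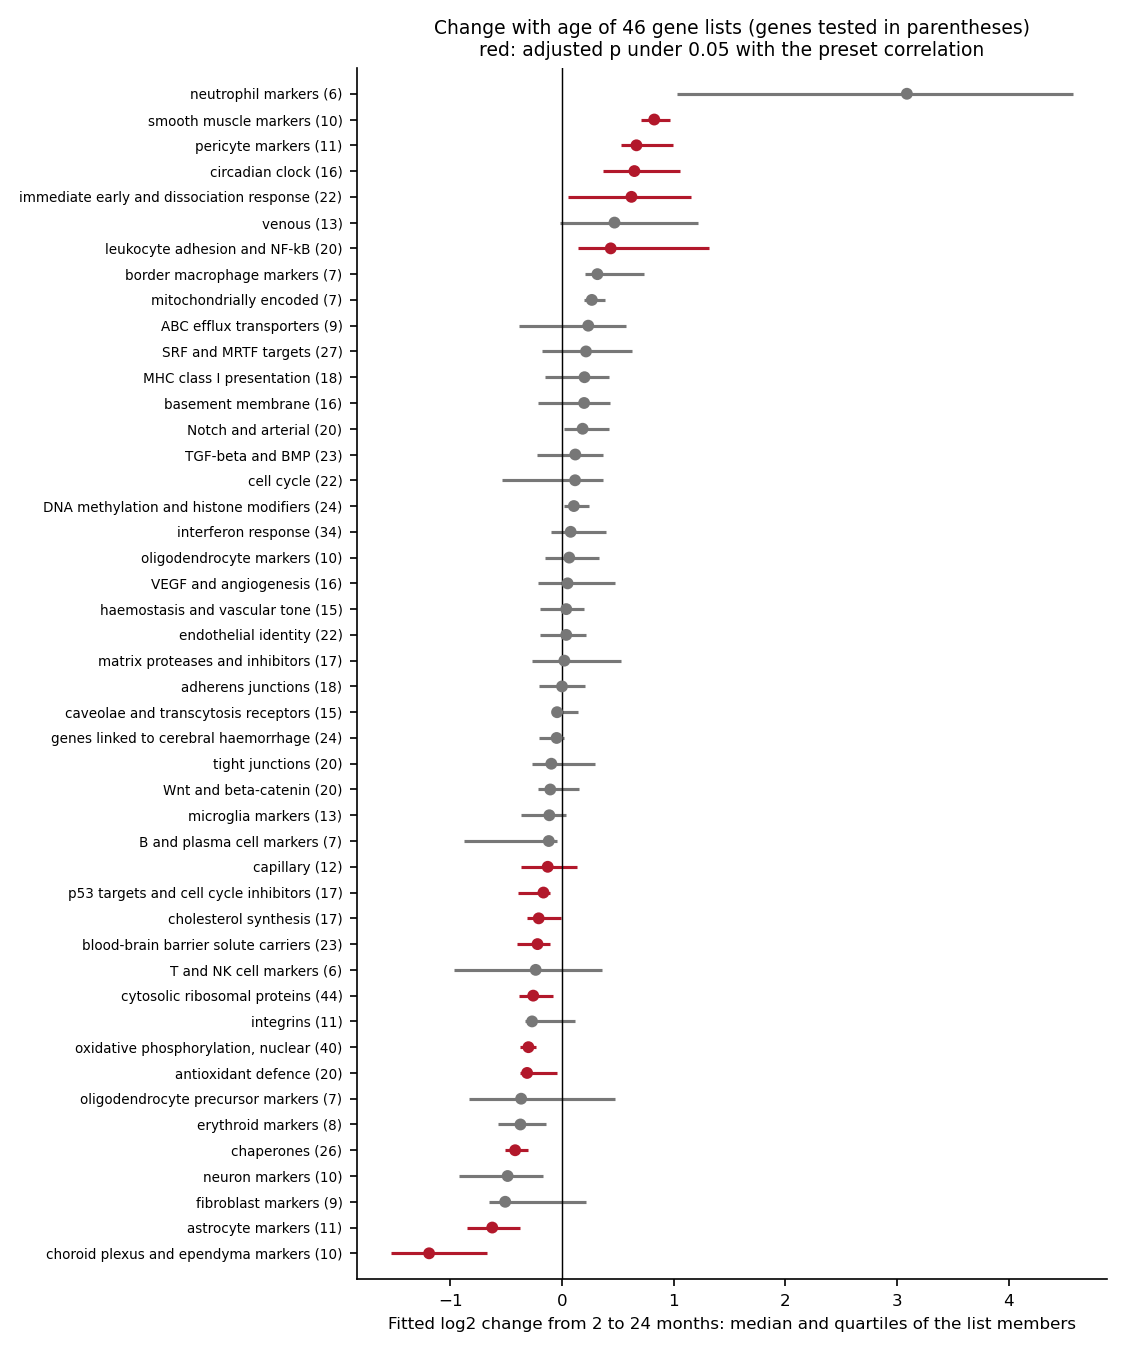
Points are the median and lines the quartiles of the fitted log2 change from 2 to 24 months over the tested members of each of 46 lists, with the 15 lists that passed camera with the preset correlation in red. The choroid plexus markers had the lowest median (-1.19 log2) and the smooth muscle markers stood at 0.83 log2.

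Markers of cells other than endothelium also moved with age. Pericyte markers were higher, 4 of 11 rising and 6 adjusted over the list alone (camera, adjusted p = 1.35e-03; adjusted p = 0.560 with an estimated correlation). They included Rgs5 (0.67 ± 0.17 log2) and the potassium channel gene Kcnj8. Smooth muscle markers were higher, 3 of 10 rising and 4 adjusted over the list alone (camera, adjusted p = 2.12e-04; adjusted p = 0.499 with an estimated correlation). The myosin kinase gene Mylk stood at 1.11 ± 0.21 log2 and Sncg at 1.21 ± 0.24 log2. Neither mural list passed in the 2-, 12- and 18-month libraries alone. Astrocyte markers were lower, 4 of 11 falling and 1 rising, 7 falling and 1 rising adjusted over the list alone (camera, adjusted p = 1.82e-03; adjusted p = 0.560 with an estimated correlation). Aldoc stood at a fitted 0.501-fold of its 2-month level at 24 months. Choroid plexus and ependyma markers were lower, 5 of 10 falling and 6 adjusted over the list alone (camera, adjusted p = 9.28e-03; adjusted p = 0.624 with an estimated correlation). The autotaxin gene Enpp2 stood at -1.24 ± 0.35 log2 and the chloride channel gene Clic6 at -1.57 ± 0.41 log2. Both genes turned in sign in the 6- and 24-month libraries alone, and they and Aldoc lost their calls with reads outside genes as a covariate.

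Of the neutrophil markers Retnlg alone rose (mean 0.229 CPM), while 2 of 6 rose adjusted over the list alone and the group did not pass (adjusted p = 0.0868). For the other marker lists no member passed over all genes or adjusted over the list alone with edgeR, and none of the lists passed. Their adjusted group p was 0.158 for 9 fibroblast markers, 0.294 for 10 oligodendrocyte markers, 0.314 for 7 oligodendrocyte precursor markers, 0.294 for 10 neuron markers, and 0.506 for 13 microglia markers. It was 0.410 for 7 border macrophage markers, 0.773 for 6 T and NK cell markers, 0.385 for 7 B and plasma cell markers and 0.294 for 8 erythroid markers. Among the list members named, calls on the slope also ended in some of the 30 fits without 1 library: Bmx and Tcf7 in 15 each, Itgb5 in 12, Retnlg in 9, Alpl and Ifi35 in 7 each, Col18a1 in 5 and Sox18 in 3. Abcc1, Actg1 and Cst3 lost theirs in 2 fits each, and Enpp2, Heg1, Ifit2, Kcnj8 and Selp in 1 each.

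Each later age was also set against 2 months, to place the changes in time. At 6 months 686 genes were higher and 790 lower, at 12 months 232 and 263, at 18 months 1697 and 1466, and at 24 months 819 and 587. Lypd1, a membrane-anchored modulator of nicotinic receptors (chromosome 1, 125867622 to 125913101), went from 6.83 ± 1.39 CPM at 2 months to 23.6 ± 3.73 CPM at 6 months and 39.3 ± 7.77 CPM at 24 months, a rise of 2.52 ± 0.16 log2 over the whole span (adjusted p = 4.89e-12). Fmo2, a flavin monooxygenase gene, was 1.49 ± 0.11 log2 higher at 24 months, and Rasgrf2 was 3.62 ± 0.26 log2 and Ankdd1b 1.99 ± 0.15 log2 higher at 18 months. Aplnr was the leading falling gene at all 4 ages, at -3.24 ± 0.29 log2 at 6 months and -5.09 ± 0.32 log2 at 24 months. The other leading falling genes were Nrep (-1.34 ± 0.10 log2) and the protease inhibitor gene Serpine2 (-1.62 ± 0.17 log2) at 24 months and Htra1 (-1.42 ± 0.13 log2) at 18 months. At the younger ages they were the actin-bundling gene Lcp1 (-1.55 ± 0.17 log2) and the tetraspanin gene Tspan18 (-1.31 ± 0.17 log2) at 12 months, and Cxxc5 (-0.95 ± 0.12 log2), a Wnt feedback gene, at 6 months. Cystm1 was 1.10 ± 0.09 log2 higher at 12 months. With reads outside genes as a covariate 214 genes differed at 18 months, and without the 3 female libraries of 6 months 220 differed at 6 months. The 6-month count was 862 with the longer-gene share as a covariate and 737 to 2184 without 1 library, and the 12-month count was 826 with that covariate, 902 with DESeq2 and 223 with only the 12 libraries compared. All 4 comparisons share the 2-month libraries, so their overlaps were not compared.

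**Figure D4:**
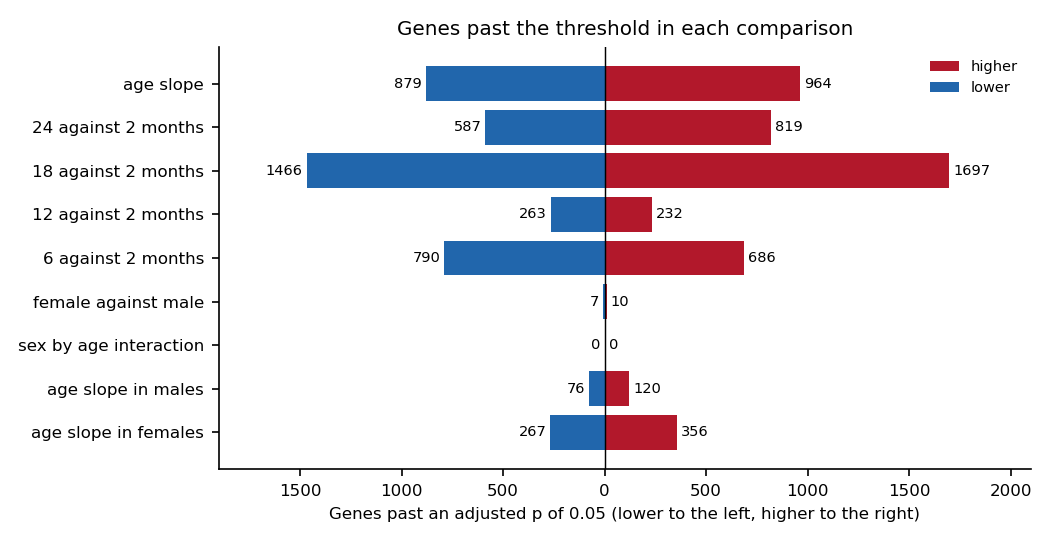
Bars give the number of genes past an adjusted p of 0.05 in each comparison (y axis), with higher genes to the right and lower genes to the left of 0 on the x axis. The 18-month comparison had 1697 higher and 1466 lower genes, and the interaction of sex with age had 0.

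For 2989 genes the age course departed from a straight line (edgeR, 3 terms tested together). The genes of lowest p were Max, the partner of the Myc transcription factors, the RNA-binding gene Raly, the lysosomal saposin gene Psap, the splicing factor gene Prpf19 and the endosomal GTPase gene Rab5c. Max (chromosome 12, 76937269 to 76962201) was at 13.8 ± 4.77 CPM at 2 months, 153.9 ± 32.8 CPM at 6 months, 14.4 ± 4.20 CPM at 12 months, 30.2 ± 7.36 CPM at 18 months and 101.9 ± 16.1 CPM at 24 months (adjusted p = 1.37e-13). Raly was also highest at 6 and 24 months, at 13.9 ± 5.62, 78.4 ± 11.6, 13.7 ± 2.77, 24.6 ± 4.29 and 58.7 ± 6.62 CPM. Psap was highest at the same ages, at 448.5 ± 106, 923.2 ± 79.6, 338.4 ± 51.2, 400.8 ± 71.9 and 944.5 ± 90.1 CPM. In a contrast chosen after these values were seen, 955 genes differed between the 12 libraries of 6 and 24 months and the other 18, 463 higher and 492 lower. With the longer-gene share as a covariate 1466 genes departed from the line, and with reads outside genes 905.

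Between females and males, with age as a factor, 17 genes differed, 10 higher and 7 lower in females (n = 15 of each sex). Besides Xist, the genes higher in females with the lowest p were the X-linked protocadherin gene Pcdh11x (2.52 ± 0.34 log2), Vamp7 (0.48 ± 0.07 log2), the X-linked helicase gene Ddx3x (0.39 ± 0.06 log2), which escapes X inactivation, and the interferon-inducible gene Mndal (0.51 ± 0.09 log2). Those higher in males were the Y-linked Ddx3y, Kdm5d, Uty and Eif2s3y and the Y-linked pseudogene Gm4017. Gm4017 lies within Ddx3y (chromosome Y, 1260771 to 1286629), Mndal overlaps the related gene Ifi203, and the counts are not split by strand, so these values are uncertain. Of the 46 lists 21 passed camera on sex, 4 higher and 17 lower in females. With an estimated correlation SRF and MRTF targets alone passed (lower in females, median -0.18 log2, camera adjusted p = 2.83e-04, and 0.0319 with an estimated correlation). Their members Acta2, Tagln, Cnn1, Myl9 and Tpm2 are also on the smooth muscle marker list, which was lower in females too. Whether the difference lay in endothelial or in smooth muscle cells was not tested. Immediate early genes were lower in females (median -0.31 log2, adjusted p = 7.91e-09), with 7 of 22 lower adjusted over the list alone and none over all genes, and adjusted p = 0.265 with an estimated correlation. Smooth muscle markers were lower in females (median -0.54 log2, adjusted p = 6.73e-06; adjusted p = 0.282 with an estimated correlation), and microglia markers too (median -0.47 log2, adjusted p = 3.48e-04; adjusted p = 0.485 with an estimated correlation). Clock genes were lower in females, 6 of 16 adjusted over the list alone (median -0.47 log2, adjusted p = 3.09e-04; adjusted p = 0.282 with an estimated correlation). Interferon response genes were higher (median 0.10 log2, adjusted p = 2.30e-05; adjusted p = 0.412 with an estimated correlation).

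None of the 16844 genes tested passed for a slope on age that differed between the sexes (edgeR, 0 genes, 916 at an unadjusted p under 0.05; 0 with DESeq2 and 0 with limma-voom), and without the filter on low counts 7 genes did. In the male libraries alone 120 genes rose and 76 fell with age, and in the female libraries alone 356 rose and 267 fell. Of these, 50 rose in both sexes where independent lists would share 2.54, and 33 fell in both where 1.20 would be shared. Over all genes tested the male and female slopes had a Pearson r of 0.366 and a Spearman rho of 0.420, across genes that are not independent replicates. The slope of Ntn4 passed in both sexes, with an adjusted p of 7.50e-06 in males and 2.48e-03 in females, as did those of Aplnr (4.18e-04 and 1.30e-03) and Oas2 (4.18e-04 and 2.48e-03). Mfsd2a, Cldn5 and Vwf passed in females (adjusted p = 4.51e-03, 0.0345 and 2.56e-03) and not in males (0.102, 0.288 and 0.0512). Their slopes were not shown to differ between the sexes (interaction adjusted p = 0.876, 0.927 and 0.879). With reads outside genes as a covariate 156 genes passed in males and 0 in females (edgeR, 919 at an unadjusted p under 0.05; 81 with DESeq2 and 13 with limma-voom).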

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

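The tests of a shared batch, of length in the genes without overlap, of length at 18 months and of a lower endothelial share, and the list tests without some libraries, were chosen after the results were seen, and the other tests in this part before.

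Within the groups of 6 libraries, 13 of 115 groups of values held a library far from the other 5, where chance gives about 1 in 20. The male library of 2 months, replicate 1, stood apart in 4 of them: its score of smooth muscle markers was 5.15 (3.40 to 4.00 in the other 5), of astrocyte markers 6.27 (5.14 to 5.49) and of microglia markers 6.83 (4.04 to 4.88), all as mean log2 CPM. Its Mfsd2a was at 809.6 CPM (1075 to 1209). Not all lists were among these 115 groups: the same library also stood apart in oligodendrocyte markers, at 5.68 (2.86 to 3.41), and their precursors, at 3.11 (1.58 to 2.15). The pericyte score of the male 6-month library, replicate 1, was 4.38 (3.54 to 3.80). H2-Q6 stood apart at 3 ages. It was at 472.2 CPM in the female 6-month library, replicate 4 (18.7 to 37.5 in the others), 100.7 CPM in the male 12-month library, replicate 3 (42.0 to 54.9), and 301.4 CPM in the male 24-month library, replicate 2 (104.3 to 161.3). Vwf was at 309.5 CPM in the male 2-month library, replicate 3 (122 to 167.5), Slc2a1 at 3899 CPM in the male 12-month library, replicate 1 (4756 to 4938), and Max at 69.8 CPM in the female 24-month library, replicate 4 (105.2 to 114). The male 24-month library, replicate 1, had 50464366 counts in genes (35868349 to 37988419), and the female 6-month library, replicate 5, had 4.40% unmapped reads (3.04 to 3.54%).

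For 8 lists the slope on age differed between the sexes with the preset correlation: interferon response (adjusted p = 2.56e-12), MHC class I presentation (2.73e-09), nuclear oxidative phosphorylation (3.74e-07), antioxidant defence (2.61e-05), and microglia markers (1.81e-03). The others were erythroid markers (2.42e-03), cytosolic ribosomal proteins (2.58e-03) and choroid plexus markers (4.10e-03). None passed with an estimated correlation. Without the 3 female libraries of 6 months, interferon response (8.11e-12), MHC class I presentation (2.64e-06), microglia markers (2.54e-04), choroid plexus markers (1.71e-03) and antioxidant defence (0.0147) still differed, each at 0.766 with an estimated correlation. Oxidative phosphorylation (0.135), erythroid markers (0.189) and the ribosomal list (0.663) did not. The interferon and MHC class I slopes were higher in males than in females. In males the 24-month library, replicate 2, scored 7.29 (6.60 to 6.69 in the other 5 of that age) and 7.91 (7.10 to 7.38). Without that library as well, their adjusted p was 2.08e-06 and 5.25e-03, and no list passed with an estimated correlation. Without the male 2-month library that stood apart in microglia markers, that list no longer differed (0.317, and 0.135 also without the 3 female libraries of 6 months).

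Of all reads, a median of 6.22% lay outside genes, 10.4% at several places and 3.96% over several genes, and the comparisons did not use them.

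A first pattern is that 955 genes stood apart in the 12 libraries of 6 and 24 months, with Max 2.78 log2 higher there, and 18 of them had no overlap between these 12 libraries and the other 18. Reads outside genes are argued against as the whole cause, since with their share as a covariate the median size of the difference kept 0.931 of its value. Gene length bias stays open for the wider set, whose median size fell to 0.650 of its value with the longer-gene share as a covariate. The 18 genes without overlap kept 0.938 of theirs. They were picked by this same difference and had a median size of 1.64 log2, against 0.435 log2 over the 955, so they do not decide. A library batch shared by 6 and 24 months could account for the pattern and cannot be told apart from age, because no label gives one: the median 24- against 6-month change in these genes was -0.171 log2 in the direction of the difference, 0.393 of its size. A biological course in age with peaks at 6 and 24 months stays open as well.

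A second pattern is the larger number of genes at 18 months, where 3163 differed from 2 months. Gene length bias is neither shown nor excluded: with the longer-gene share as a covariate 3017 genes passed (2063 of the 3163), and the count went from 2.14 to 1.37 times the highest of the other ages while the 24-month count rose from 1406 to 2204. Reads outside genes, highest at 18 months, stay open: across genes, the change per SD of that share within ages correlated with the 18-month change at a Pearson r of 0.194. With the share as a covariate the median size over the 3163 genes went from 0.634 to 0.366 log2 and its median SE from 0.154 to 0.242, so that the calls ended both by smaller estimates and by wider errors, and 89.9% of the genes had the same sign. A technical difference in the RNA, the instrument (if the 6 single-end libraries were those of 18 months) and a biological change with age cannot be told apart here, because each would move with the group.

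The last pattern is the rise of pericyte and smooth muscle markers, by 0.752 log2 over 22 months (permutation p = 2.82e-03, n = 30). A lower share of endothelial cells would raise the markers of all other cells. Astrocyte and choroid plexus markers changed by -0.698 log2 (permutation p = 0.0148), but these lists were picked after they were seen to fall. The difference of the scores changed by 1.45 log2 (permutation p = 1e-05, the smallest these permutations can give), and that p does not allow for the choice. Of the lists left out, border macrophage (median 0.32 log2), oligodendrocyte (0.07 log2) and neutrophil markers (3.09 log2) lay above 0 and the other lists below. None of them passed, so a lower endothelial share stays open. More mural cells in the samples of older mice may account for the rise: 20 of 21 mural markers had a positive slope, and within ages their median correlation was 0.494. Higher expression per mural cell, or in endothelial cells, would look alike and stays open.

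Each count was set against 100 splits of the libraries, the real one included. The real split alone reached its count for the age slope (1843, highest other 1175), 24 against 2 months (1406, 447), 18 against 2 months (3163, 1255) and 12 against 2 months (495, 105). It also did so for 6 against 2 months (1476, 1469), the departure from a line (2989, 4), sex (17, 1), the slope in males (196, 1), the slope in females (623, 33) and the lists on sex (21, 20). That is 1 of 100 in each case, the fewest that 100 splits can give, so a random grouping is unlikely for these. At 6 months and for the lists on sex the margin over the next split was small. Sex-linked genes such as Xist separate the real split by sex in advance, so the gene count on sex says little. At 6 months the highest other split kept the female libraries apart by age, and without the 3 female libraries of 6 months 220 genes passed. For the 15 lists on age 8 of 100 splits gave as many (highest other 17), so a random grouping is not excluded for them. For the interaction the count was 0 (edgeR, 916 at an unadjusted p under 0.05; 0 with DESeq2 and 0 with limma-voom), which all 100 splits reach by design (highest other 1), so the splits say nothing about it.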

How the results depend on the processing

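The settings with a term for 6 and 24 months, with only some ages, without the 3 female libraries of 6 months, or with the longer-gene share were chosen after seeing the data. No paired analysis was possible because the labels give each sample its own identifier, and replicate numbers follow only the order of the samples. With the share of reads outside genes as a covariate 402 genes passed on the age slope (360 of the 1843), 214 at 18 months (191 of the 3163), 905 for the departure from a line and 0 for the slope in females (edgeR, 919 at an unadjusted p under 0.05; 81 with DESeq2, 13 with limma-voom). With the longer-gene share as a covariate 862 genes passed at 6, 826 at 12 and 2204 at 24 months, 1466 for the departure, 415 for the slope in males and 37 for sex. Without the 3 female libraries of 6 months 220 passed at 6 months, 1746 for the departure and 31 for sex. With 2 surrogate variables 2582 passed at 24 months, 620 for the slope in males and 30 for sex. DESeq2 gave 902 at 12 months, 1773 and 628 for the slopes in females and males and 55 for sex. The age slope gave 713 genes without 18 months, 886 without 2 months and 461 in the 6- and 24-month libraries alone. The slopes in females and males gave 1779 and 49 in the 2-, 12- and 18-month libraries, with fewer libraries in the fit. The term for 6 and 24 months gave 3719 for the slope in females and, on the age slope, 1741 of the 1843 genes still passed. With log2 of age 304 passed for the slope in males. Without the filter 967 passed at 6 months and 7 for the interaction. With only the 12 libraries compared 223 passed at 12 months. For sex 10 passed without 18 months and 9 without 24 months. With an estimated correlation 1 list passed on age and 1 on sex, and with fry 1 on sex. On age the ribosomal, antioxidant, cholesterol, astrocyte and choroid plexus lists lost their calls with fry, and the other lists called by camera kept theirs. Fry also called Notch and arterial genes (adjusted p = 6.39e-04) and modifiers of DNA methylation and histones (adjusted p = 0.0424), which camera did not. Unless the setting has fewer libraries or genes, the cause was not tested.

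Leaving out 1 library at a time gave 328 to 571 genes at 12 months, 737 to 2184 at 6 months, 179 to 665 for the slope in females, 74 to 278 for the slope in males, 1894 to 3730 for the departure and 14 to 26 for sex. The counts moved by over 1.5 times at 12 months without 2-month replicate 6 (328), and at 6 months without 2-month replicates 4, 5 and 6 (944, 959 and 888) or 6-month replicates 4, 5 and 6 (737, 762 and 789), all female. For females it did so without replicates 4, 5 and 6 of 18 months (350, 362 and 392) and of 2 months (179, 325 and 225) and 24-month replicate 4 (388), for males without 2-month replicates 2 and 3 (74 and 117) and 24-month replicate 1 (92), for the departure without 18-month replicate 5 (1894) and for sex without 2-month replicates 2 or 3 (26 each). On the age slope it stayed within 1326 to 2036, at 18 months 2319 to 3396 and at 24 months 1039 to 1516. The lists stayed within 14 to 17 on age and 17 to 23 on sex.

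Signs turned in 11 cases. In the 6- and 24-month libraries alone Clic6 (0.28 log2), Enpp2 (0.25 log2), Kl (0.53 log2) and the choroid plexus list (adjusted p = 0.357) turned, and Kl was at 0.0010 log2 without 2 months. Itgb5 was at -0.16 log2 in the 2-, 12- and 18-month libraries. Lists that turned were antioxidant defence on age (0.768) and oxidative phosphorylation on sex (1.43e-03) with reads outside genes, the ribosomal list on age (0.754) with the longer-gene share, and the ribosomal list (6.26e-03) and MHC class I (0.841) on sex without the 3 female libraries of 6 months. The cause was not tested. No scaling moved the median of all genes by over 0.1 log2, and RLE scaling kept all 168 calls of named genes. Reads outside genes as a covariate kept 92 of these 168 and leaving out 2 months 64 of 139. Of 129 named genes called on the age slope, 94 kept the call in each fit without 1 library. In the simulations 13.4% (interaction) to 77.6% (sex) of the genes changed 1.5-fold were recovered, so changes of that size can be missed.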

Other observations

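The test of tip cell genes was fixed before its result was seen. The counts between other pairs of ages were made after the age courses were seen. Between neighbouring ages, 12 against 6 months gave 114 genes higher and 204 lower, 18 against 12 months 1091 and 1133, and 24 against 18 months 86 and 126, and 24 against 6 months gave 255 and 235 (edgeR, adjusted p under 0.05). Xist was at 1.83 CPM in the male 12-month library, replicate 3, and at 1.47 CPM in the male 18-month library, replicate 2, where the lowest female library had 21.2 CPM, and both had Y-linked Ddx3y (115.5 and 131.6 CPM).

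Apln is expressed in sprouting tip cells, and Aplnr encodes the receptor for apelin. A hypothesis is that the fall of both after 2 months may reflect fewer tip-like endothelial cells. Over the 17 other tip cell genes tested the median change at 12 against 2 months was -0.107 log2, with 2 genes lower, Trp53i11 and Col4a2, and 0 higher (edgeR), and p = 0.0445 with an estimated correlation. The median change was -0.24 log2 at 6 months and -0.05 log2 at 24 months. With 2 of 17 genes past the threshold and a small median these values do not decide, and the hypothesis stays open.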
